A study of Mus musculus with 6 samples.

How the data were processed

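RNA was measured in whole small intestine of mouse embryos late in gestation (E18.5), with 3 control samples, labelled wild type, and 3 samples of an E-cadherin conditional knockout (cKO). E-cadherin, the product of Cdh1, is the main calcium-dependent adhesion molecule of epithelial adherens junctions. The tissue was rinsed, kept in an RNA preservative and extracted on silica columns, and the total RNA was labelled with biotin by a whole-transcript sense protocol, all per the labels' protocols. The series design text names Affymetrix Mouse Gene 1.0 arrays and the software dChip. The dChip version, its background correction, normalization and expression model are not given in the sources used here, and neither are the driver of the recombination, the deleted exons and the embryos' sex.

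The deposited table holds 1 value per probe set and array, 35512 probe sets in all, with 2 decimals. The values run from 0 to about 14 and were read as log2 expression values made by the authors, from that range, since the labels do not name the scale. Fold changes given here rest on that reading. Values were used as deposited, with no further normalization. The array medians were 6.44, 6.45 and 6.50 in controls 1, 2 and 3 and 6.48, 6.17 and 6.45 in cKO 1, 2 and 3. Array values carry no read depth, and the number of arrays limits the precision. A value of 0 appeared on every array for 1 probe set, and 0 of the genes called changed had a value at 0.

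Probe sets were named through the platform annotation. Of the 35512 probe sets, 21789 had 1 gene symbol, 1621 had several and 12102 had none listed, so these last are unnamed here and not without a gene. Symbols were updated through the gene identifier for the 21698 single-symbol probe sets found in the reference gene table (GRCm38.p6), and the others kept the annotation's symbol. Where a gene had several probe sets (999 genes), the brightest over the 6 arrays was used, which left 19938 genes. The table was used for names only, and no coordinates are given because the labels name no genome build. The labels do not say whether the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical.

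The comparison of cKO with control was fixed before the data were examined, as follows. Each gene was tested with limma (lmFit and eBayes, two-sided, no covariate, all 6 arrays), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Differences are cKO minus control on the log2 scale, each with limma's moderated standard error (SE). Group values are means ± SD. Cdh1 was also tested with an exact two-sided permutation test, whose smallest possible p for 3 against 3 is 0.1.

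Gene lists were fixed before the data were examined, 50 in all, from textbook knowledge of the intestine, of neighbouring organs and of signalling pathways. They cover cell junctions and keratins, epithelial identity, enterocyte function, secretory and stem cells, signalling, the cell cycle, stress, metabolism, immune cells, mesenchyme, nerves and vessels, position along the gut, and pancreas, stomach, liver and squamous epithelium. The 49 lists with at least 5 measured members were tested with limma's camera against all other genes, with the preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. The list of sex-linked genes had 4 measured members and was not tested. Camera with a correlation estimated for each list and fry were run beside it. Fry, used here in its directional form, tests whether the members of a list shifted in 1 common direction. It does not test whether they changed more than other genes, so its calls answer another question than those of camera. A list that fry did not call may still hold members that changed in both directions. With the estimated correlation 0 of the 49 lists passed the threshold (12 at unadjusted p under 0.05), and the lowest adjusted p was 0.116, whereas fry called 30. Of the listed symbols, 82 found no measured gene and were not analysed here, and 51 genes belong to more than 1 list. The counts of members past the threshold are given over all genes and, where said, adjusted over the list alone.

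The named genes follow a rule fixed before the data were examined. They are Cdh1, the 12 genes with the largest and the 12 with the most negative log2 change among genes past the threshold whose 3 cKO values all lay above or all below the 3 control values, up to 4 members with the smallest p of each list, and a fixed set of single genes (Cdh2, Cdh3, Cdh17, Ctnnb1, Ctnnd1, Jup, Lgr5, Axin2, Myc, Muc2, Chga, Lyz1, Alpi, Epcam, Vil1, Mki67 and Xist). Cdkn1a and Ddx3y were also in that set and were not analysed here. Genes outside the rule are said to have been chosen after their values were seen.

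As a measure of background, chosen after the data had been seen, the 95th percentile of 1228 olfactory, vomeronasal and taste receptor genes was taken on each array. Where all arrays of 1 group lay at or below it, the fold is given as at least the other group's mean over the mean of that level on the arrays of the first. Probes differ in their own background, so a gene below this level may still be expressed.

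The alternatives were quantile normalization, median centring of each array, 16 added to the linear values before log2, leaving out the dimmest 25% or the dimmer 50% of genes, the mean of a gene's probe sets, every probe set tested on its own, eBayes with an intensity trend or robust hyperparameters, array weights, a minimum of 1.5-fold, the replicate number as a block, and each of the 6 arrays left out in turn. Cyclic loess normalization was added after the data had been seen. The scripts were tested on simulated data with 10 runs of 200 changed genes among 19938, drawn for the comparison of cKO with control. Of the simulated 2-fold changes 80.7% were recovered and of the 4-fold changes 99.0%, and 6.50% of the called genes were false. Runs without changed genes called at most 1 gene, and a list shifted by 0.5 was called in 10 of 10 runs. The simulated genes were drawn independently, with the same noise on every array. Real members of a list moved together (estimated correlation of 0.66 in the cell cycle list). These runs therefore check the scripts and give no error rate for correlated genes or for the list calls. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with matplotlib 3.10.9 for the figures.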

Results

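Gene expression was compared between small intestine of control embryos and of embryos with a conditional knockout of E-cadherin (cKO) shortly before birth (E18.5), when the villi are already formed, with 3 arrays per group. The comparison asks which transcripts differ in the intestine when E-cadherin is removed. Correlations between arrays, over genes, ranged from 0.981 to 0.987 among controls, from 0.972 to 0.978 among cKO arrays and from 0.929 to 0.966 between the groups. The first principal component held 58.9% of the variance and separated the groups. On cKO 2, dim genes lay lower than elsewhere: 1228 genes for olfactory, vomeronasal and taste receptors, which serve as a measure of background, shifted by -0.37 (median, log2, relative to the control mean), against -0.06 to 0.09 on the other arrays.

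Cdh1 itself (probe set 10575052) read 9.86, 9.82 and 10.15 in controls 1, 2 and 3 and 9.70, 8.38 and 8.91 in cKO 1, 2 and 3. The cKO mean was 9.0 ± 0.66 (SD, n = 3) against 9.94 ± 0.18 (SD, n = 3), a difference of -0.95 (SE 0.31, 95% interval -1.67 to -0.22) that did not pass the threshold over all genes (limma adjusted p = 0.088). All 3 cKO values lay below all 3 control values, which in the exact two-sided permutation test gives p = 0.1, the smallest this design allows. The cKO 1 value lay only 0.24 below the control mean, while cKO 2 and cKO 3 lay 1.56 and 1.03 below it. Without cKO 1 the difference was -1.30 and passed (adjusted p = 0.012). The position of the probes relative to the deleted part is not given in the sources used here, and probes outside it may not report the deletion.

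The cKO intestine differed from the control in 2825 of 19938 genes, 1358 higher and 1467 lower, a balance that turned with the scaling of the arrays (1830 and 1413 with quantile normalization, 1490 and 1091 with median centring). The 3 enterocyte lists were lower by camera with a preset correlation: the digestive enzyme gene Lct (lactase) fell by 3.16 on the log2 scale, and the list of fatty acid oxidation was lower as well. The list of fetal and regenerating epithelium was higher, led by Anxa10 (an annexin of gastric epithelium), as were those of the extracellular matrix, smooth muscle, macrophages and growth factor feedback. With an estimated correlation none of these lists passed (adjusted p of 0.116 or more). Of 21 general epithelial identity genes 5 fell, while Epcam and Cdh17 did not pass the threshold. In all 2825 genes the 3 cKO values lay apart from the 3 control values, as did those of 7052 genes (35.4%) among those tested, where chance gives 10%. Of the changed genes, 356 were higher and 517 lower by at least 2-fold as measured. Both groups of 115 changed genes lay at or below the level under which 95% of the receptor genes fall (5.72 to 6.36 over the arrays), called background here, as did the controls of 165 others and the cKO arrays of 85. Leaving out control 2, control 3 or cKO 3 reduced the 2825 genes to 1226, 1505 and 1517.

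The largest measured increases were in Ly6d, a cell surface protein of stratified epithelium, from 5.49 ± 0.02 to 11.37 ± 0.43 (SD, n = 3 each), and in Anxa10, from 4.25 ± 0.40 to 10.04 ± 0.74 (SD, n = 3 each). The differences of 5.88 (SE 0.21, adjusted p = 0.00017) and 5.79 (SE 0.37, adjusted p = 0.00058) depend on controls at background, and against that level they are at least 34.4-fold and 13.7-fold. Sprr1a, a precursor of the squamous cornified envelope, rose by 4.19 (SE 0.31) and Il1rn, the interleukin-1 receptor antagonist, by 3.99 (SE 0.28). Gprc5a rose by 3.71, Plet1, a marker of progenitor and healing epithelium, by 3.21, the stromelysin gene Mmp10 by 3.14 and the claudin gene Cldn4 by 3.08, each with adjusted p at or below 0.0013. The controls of Sprr1a, Il1rn, Gprc5a, Mmp10, Ly6g and Ada were also at background, so their differences and their order are not exact (at least 10.2-fold for Sprr1a, 5.32-fold for Il1rn, 6.83-fold for Gprc5a, 5.59-fold for Mmp10, 2.26-fold for Ly6g and 6.54-fold for Ada). The same holds for the controls of Egr1, Ereg, Il1b, Ptgs2, Plk3 and Gal. The remaining 4 of the 12 measured increases varied more between arrays. The antimicrobial lectins Reg3b and Reg3g rose by 4.0 (SE 0.95) and 3.72 (SE 0.74), the neutrophil gene Ly6g by 3.28 (SE 0.68) and Ada, adenosine deaminase, by 3.11 (SE 0.62). Reg3b was not called without control 2, control 3, cKO 2 or cKO 3 (adjusted p = 0.108, 0.126, 0.076 and 0.092) and Reg3g not without control 2, control 3 or cKO 3 (0.060, 0.073 and 0.052). The call of Ly6g was lost without control 1, 2 or 3 (0.059, 0.076 and 0.075) and that of Ada without control 2 or 3 (0.069 and 0.070).

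Among the 12 largest measured decreases, Fbp1, a gluconeogenic enzyme, went from 10.55 ± 0.84 to 5.75 ± 0.13 (SD, n = 3 each), a difference of -4.79 (SE 0.37, adjusted p = 0.00077). Pck1, the rate-limiting enzyme of the same pathway, fell by 3.47 (SE 0.52). Acot3, a peroxisomal acyl-CoA thioesterase, fell by 4.35 (SE 0.34), the retinol dehydrogenase gene Sdr16c5 by 3.50, the lipid droplet gene Hsd17b13 by 3.39 and the phosphate transporter gene Slc34a3 by 3.42. Adh1, an alcohol dehydrogenase gene, fell by 3.41 (SE 0.41). Nox4 and Mcoln3, a lysosomal channel gene expressed in neonatal enterocytes, both fell by 3.34, and the meiotic gene Sycp3 by 3.68 to 2.94 ± 0.38 (SD, n = 3). These 10 genes had adjusted p at or below 0.0060. The cKO values of Fbp1, Acot3, Sdr16c5 and Sycp3 lay at background, so that against this level they were lower by at least 23.3-fold, 6.78-fold, 4.10-fold and 1.53-fold, and their order is not exact. Afp, the alpha-fetoprotein gene, fell by 3.61 (SE 0.75), a call lost without control 1, control 2 or cKO 3 (adjusted p = 0.055, 0.080 and 0.061). Mptx1, a mucosal pentraxin gene, differed by -3.69 (SE 0.96, adjusted p = 0.043) and was not called with array weights (0.097) or when control 1, 2 or 3 or cKO 1 or 2 was left out (0.068, 0.075, 0.120, 0.101 and 0.103).

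**Figure D1:**
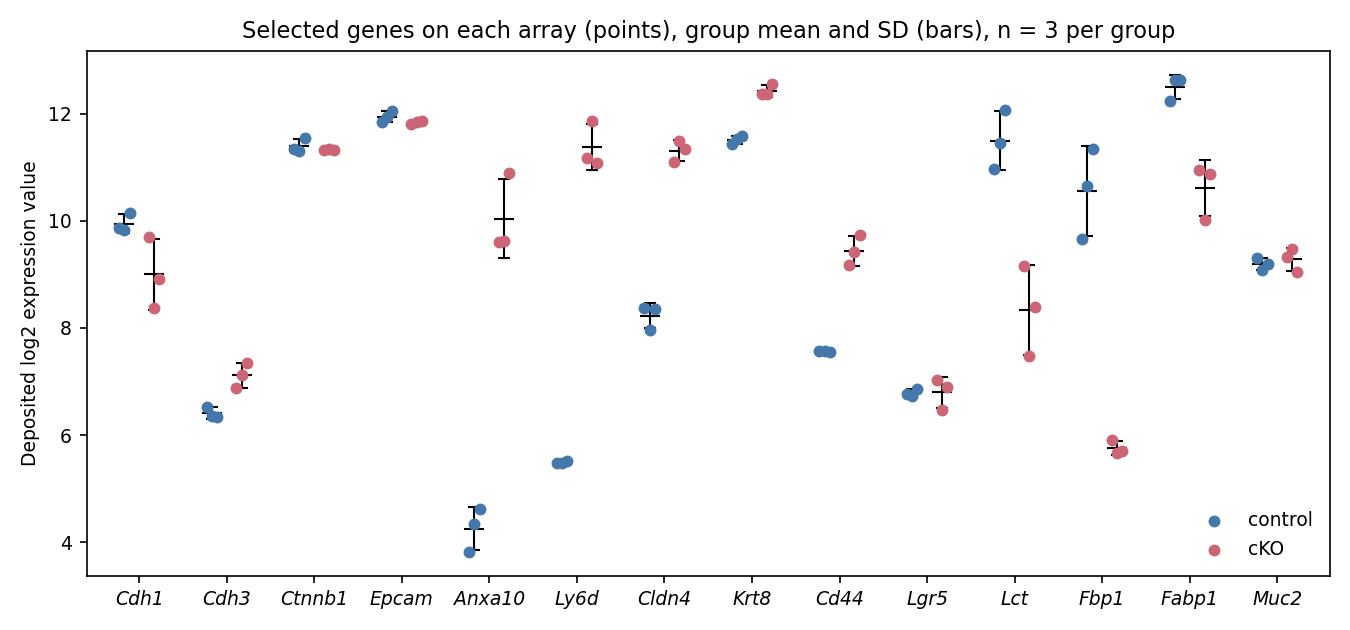
Deposited log2 expression values (vertical axis) of 14 genes on each array, with controls in blue and cKO in red; bars show the group mean and SD, n = 3 per group. Cdh1 on cKO 1 reads 9.70, near the controls, while Ly6d, Anxa10 and Cldn4 lie higher and Lct, Fbp1 and Fabp1 lower on all 3 cKO arrays.

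Of the 49 lists tested, 23 were higher and 7 lower in cKO by camera with the preset correlation. With an estimated correlation 0 passed (12 at unadjusted p under 0.05). Fry, which tests for a shift in 1 direction and not against other genes, called 30, of which 27 are among those called by camera. For 28 of the 30 called by camera, the mean of the members on each cKO array lay beyond that on each control array. These lists were selected on the same arrays, so this is no separate evidence for them. The 3 enterocyte lists were lower. Of 24 genes of lipid absorption and lipoproteins, 20 fell and 1 rose (3 rose and 21 fell adjusted over the list alone), with a median of -1.18 (camera adjusted p = 8.9e-10, and adjusted p = 0.29 with an estimated correlation). Fabp2, an intestinal fatty acid binding protein, fell by 1.68 (SE 0.14), Apoc3 by 1.73 (SE 0.16), Lrat, which esterifies retinol, by 2.16 (SE 0.19) and Mogat2, which rebuilds triglycerides, by 1.33 (SE 0.14). The member that rose was Pparg (0.95, SE 0.14, adjusted p = 0.0053), chosen after its values were seen. Of 20 nutrient transporters, 13 fell (1 rose and 16 fell adjusted over the list alone), with a median of -1.19 (adjusted p = 2.4e-08, and 0.29 as adjusted p with an estimated correlation). They include the vitamin C transporter gene Slc23a1 at -2.85, the iron transporter gene Slc11a2 at -1.57 and the cystine transporter gene Slc7a9 at -1.16. Of 22 digestive enzyme and brush border genes, 13 fell (17 adjusted over the list alone), with a median of -0.97 (adjusted p = 2.4e-08, and adjusted p = 0.25 with an estimated correlation). Ace, a brush border peptidase, fell by 3.06 (SE 0.27), Mep1a by 2.47 (SE 0.28) and the scaffold genes Pdzk1 and Ush1c by 1.86 and 1.30. Alpi, the intestinal alkaline phosphatase, differed by -0.84 (adjusted p = 0.055).

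The lists of fatty acid oxidation and oxidative phosphorylation were called lower. Of 19 peroxisomal and fatty acid oxidation genes, 13 fell (15 adjusted over the list alone), with a median of -0.72 (adjusted p = 5.9e-09, and adjusted p = 0.29 with an estimated correlation), including Acaa2 at -1.60, Acot1 at -1.73 and Ech1 at -0.92. Of 23 oxidative phosphorylation genes, 7 fell (16 adjusted over the list alone), with a median of -0.38 (adjusted p = 4.9e-06, and adjusted p = 0.38 with an estimated correlation). Cox4i1 and Sdhb fell by 0.56 and 0.59, calls that were lost without control 2, control 3 or cKO 3 (adjusted p = 0.099, 0.081 and 0.058 for Cox4i1, and 0.10, 0.085 and 0.054 for Sdhb), and with the replicate block (0.056 and 0.051). Of 24 xenobiotic metabolism genes, 6 fell and 3 rose (list adjusted p = 0.34), with Ugt2b5 at -2.83, Ces2e at -1.66 and the glutathione transferase gene Gsta4 at 2.14. The 19 cholesterol synthesis genes included 2 that fell, among them Insig1 at -1.10 (list adjusted p = 0.16, called lower with array weights and without control 3 or cKO 2 at 0.0036, 0.0015 and 0.020). Of 14 duodenal and jejunal position genes, 5 fell and 2 rose (list adjusted p = 0.071). This list was called lower with quantile normalization, median centring and cyclic loess (0.032, 0.020 and 0.033), and without control 1, cKO 2 or the dimmer 50% of genes (0.032, 0.029 and 0.039). For the ileal and colonic list, 1 of 16 genes rose and 1 fell (adjusted p = 0.51). These were Gm2a at 1.12 and Cubn, the vitamin B12 complex receptor gene of the ileum, at -2.23.

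Of 21 identity genes shared by all intestinal epithelium, 5 fell, also adjusted over the list alone, with a median of -0.31 (adjusted p = 0.020, and adjusted p = 0.55 with an estimated correlation). The transcription factor genes Cdx2 and Gata6, which specify intestinal epithelium, fell by 0.79 (SE 0.13) and 1.09 (SE 0.20), and the membrane protease gene Prss8 by 1.26 (SE 0.14). Hnf4a fell by 0.88, a call lost without cKO 3 (adjusted p = 0.065). Epcam differed by -0.10 (95% interval -0.36 to 0.16, adjusted p = 0.59), Cdh17 by -0.15 (adjusted p = 0.51) and Vil1 by -0.31 (adjusted p = 0.19). The list itself was not called without control 3 (median -0.21, adjusted p = 0.056) or cKO 3 (median -0.26, adjusted p = 0.082).

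All 14 measured genes of the fetal and regenerative epithelium list rose, also adjusted over the list alone, with a median of 1.97 (adjusted p = 2.3e-16, and adjusted p = 0.12 with an estimated correlation). Besides Anxa10 and Il1rn they include Anxa3 at 2.15 (SE 0.14) and S100a6 at 2.66 (SE 0.22). Of the 14 genes, 6 are also in another list, among them Msln of the mesothelium list and Gja1 of the Cajal cell list. The samples were whole intestine, so the cells in which these genes or the YAP and TAZ targets rose are not known. Of 19 targets of the YAP and TAZ coactivators, 9 rose (16 adjusted over the list alone), with a median of 0.48 (adjusted p = 2.1e-09, and adjusted p = 0.12 with an estimated correlation), including F3, the tissue factor gene, at 1.94, Ajuba at 1.13 and Tead1 at 0.92. Of 18 EGFR and MAPK feedback genes, 11 rose (13 adjusted over the list alone), with a median of 0.68 (adjusted p = 1.2e-10, and adjusted p = 0.12 with an estimated correlation). The phosphatase gene Dusp4 rose by 1.76 (SE 0.10), Epha2 by 1.54 (SE 0.12) and the EGFR ligand genes Ereg and Hbegf by 2.04 and 1.02. Immediate early genes, which also respond to tissue handling, rose too: 9 of 17 (10 adjusted over the list alone), with a median of 0.43 (adjusted p = 1.0e-06, and adjusted p = 0.14 with an estimated correlation), including Nr4a1 at 2.16, Atf3 at 2.07 and Egr1 at 1.71. Of 18 epithelial-mesenchymal transition genes, 12 rose (14 adjusted over the list alone), with a median of 0.58 (adjusted p = 9.9e-10, and adjusted p = 0.18 with an estimated correlation). Fn1, Itga5, Tnc and Mmp9 rose by 1.26, 1.52, 1.38 and 1.91, genes that mesenchymal cells express as well. The squamous epithelium list did not pass (adjusted p = 0.19), with 3 of 16 genes higher, Sprr1a among them, nor did the stomach list (adjusted p = 0.79), where Anxa10 was the 1 of 15 that rose.

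Of 17 adherens junction components, 4 rose and 1 fell (6 and 2 adjusted over the list alone, list adjusted p = 0.071). The list was called without control 3 (adjusted p = 0.025) or cKO 3 (0.034) and by fry (0.020). The member that fell was Plekha7 (-0.39, SE 0.10, adjusted p = 0.039), named after its values were seen. Its call was lost with median centring, with the replicate block, tested by probe set and with any 1 of the 6 arrays left out (adjusted p = 0.053 to 0.20). Vcl, the vinculin gene, rose by 0.95 (SE 0.14) and Ajuba by 1.13 (SE 0.15). The beta-catenin gene Ctnnb1 differed by -0.07 (95% interval -0.34 to 0.19, adjusted p = 0.70), the p120-catenin gene Ctnnd1 by 0.25 (adjusted p = 0.32) and the plakoglobin gene Jup by 0.19 (adjusted p = 0.32). P-cadherin, Cdh3, rose by 0.70 (SE 0.15, adjusted p = 0.020), from 6.41 ± 0.10 to 7.11 ± 0.23 (SD, n = 3 each), and was not called without control 2, control 3 or cKO 3 (adjusted p = 0.088, 0.081 and 0.066). N-cadherin, Cdh2, differed by 0.47 (adjusted p = 0.080). Of 18 tight junction components, 5 rose (5 rose and 4 fell adjusted over the list alone, list adjusted p = 0.51), with Cldn4 at 3.08 (SE 0.16) and Cldn3 at 1.17 (SE 0.12). Of 13 desmosome and keratin genes, 8 rose (9 adjusted over the list alone), with a median of 0.77 (adjusted p = 1.5e-06, and adjusted p = 0.12 with an estimated correlation), including the simple-epithelium keratin genes Krt8 at 0.91, Krt18 at 1.19 and Krt19 at 0.77.

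The lists of secretory cell genes did not move as 1 group. Of 15 Paneth cell and antimicrobial genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.69 (adjusted p = 2.3e-05, and adjusted p = 0.24 with an estimated correlation). The mean shift was 0.77, 1.04 and 1.80 on cKO 1, 2 and 3. The median was 0.49 without cKO 3, 1.16 and 1.63 without the dimmest 25% and the dimmer 50% of genes, and 1.26 with array weights. Reg1, which is also in the pancreas list, read 10.84 on cKO 3 and 4.54 to 5.11 on the other arrays. Lyz1, the Paneth lysozyme gene, rose by 2.17 (SE 0.26), Ang4 by 1.63 (SE 0.19) and Mmp7 by 1.94 (SE 0.19). Lyz2 rose by 2.10 and is also a macrophage gene. The member that fell was the defensin gene Defa24 (-1.06, SE 0.22, adjusted p = 0.021), chosen after its values were seen and not called without control 2 or 3 or cKO 1 (highest adjusted p = 0.074). The 4 other defensin genes of the list found no measured gene, so the list does not show a gain of Paneth cells. Of 17 goblet cell genes, 2 rose and 3 fell (list adjusted p = 0.51), with Zg16 at 1.66, Tpsg1 at -1.05 and the mucin gene Muc2 at 0.09 (adjusted p = 0.71). The call of Zg16 was lost without control 2, cKO 1 or cKO 3 (adjusted p = 0.091, 0.056 and 0.085). Of 24 enteroendocrine genes, 2 fell and 1 rose (list adjusted p = 0.16, called lower by fry at 0.0097, with array weights at 0.045, without cKO 2 at 0.022 and without the dimmer 50% of genes at 0.035), with the ghrelin gene Ghrl at -0.92 and the galanin gene Gal at 1.05, and Chga differed by -0.47 (adjusted p = 0.17). Of 15 tuft cell genes, Hpgds fell by 1.69 and Alox5ap, also a leukocyte gene, rose by 1.73 (list adjusted p = 0.96).

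Stem cell markers were mixed. Of 22 genes of stem and intervillus progenitor cells, 7 rose and 1 fell (11 and 2 adjusted over the list alone), with a median of 0.35 (adjusted p = 1.7e-04, and adjusted p = 0.29 with an estimated correlation) that was 0.22 without cKO 1 and 0.52 without cKO 2. Cd44 and Prom1 rose by 1.88 and 1.11 and Tert fell by 1.34, while Lgr5, the marker of cycling crypt stem cells, differed by 0.01 (95% interval -0.36 to 0.39, adjusted p = 0.97). Of 23 canonical Wnt targets, 6 rose (7 adjusted over the list alone), with a median of 0.21 (adjusted p = 2.3e-04, and adjusted p = 0.29 with an estimated correlation) that was 0.10 without control 1, 0.08 without cKO 1, 0.46 without the dimmer 50% of genes and 0.34 with array weights. They include Myc at 1.04 (SE 0.16) and Dkk2 at 0.80, whereas Axin2, a direct readout of the pathway, differed by 0.07 (adjusted p = 0.83). Of 19 BMP and TGF-beta genes, 9 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.45 (adjusted p = 2.3e-05, and adjusted p = 0.12 with an estimated correlation). The receptor gene Tgfbr2 rose by 1.22 and its target Tgfbi by 1.09, and Bmp7 fell by 1.25. Of 29 cell cycle genes, 5 rose (22 adjusted over the list alone), with a median of 0.46 (adjusted p = 6.0e-11, and adjusted p = 0.29 with an estimated correlation). Kif23 rose by 1.01 (SE 0.16), and Mki67 differed by 0.39 (adjusted p = 0.063). The Notch list (2 of 18 higher, 1 lower, adjusted p = 0.51) and the Hedgehog list (2 of 14 higher, adjusted p = 0.071) did not pass. Of their members, Nrarp fell by 0.66, not called without control 2 (adjusted p = 0.053).

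Of 21 hypoxia and glycolysis genes, 5 rose and 1 fell (7 and 2 adjusted over the list alone), with a median of 0.28 (adjusted p = 0.0015, and adjusted p = 0.48 with an estimated correlation). Fry did not call the list (adjusted p = 0.077), the mean shift was 0.57 on cKO 1 against 0.11 and 0.12 on cKO 2 and 3, and the median without cKO 1 was 0.13. Hk2 rose by 1.93, the glucose transporter gene Slc2a1 by 1.21 and Car9 by 1.17. Of 12 heat shock genes, 4 rose (6 adjusted over the list alone), with a median of 0.44 (adjusted p = 7.7e-04, and adjusted p = 0.29 with an estimated correlation), including Hspb8 at 0.94. Of 21 p53 target and apoptosis genes, 6 rose and 2 fell (list adjusted p = 0.23), with Plk3 at 1.13, Plk2 at 0.88 and Perp, which encodes a desmosome-associated protein, at -0.93. Of 21 genes of the unfolded protein and integrated stress response, 2 rose and 4 fell (list adjusted p = 0.63). List median, mean and test differed in sign for 5 lists, those of tight junctions, Notch, p53, mast cells and stomach, none of which passed the threshold.

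Of the immune lists, those of macrophage, cytokine and neutrophil genes were called higher. The interferon list was called lower, a call that was lost without control 2. Of 19 macrophage genes, 11 rose (14 adjusted over the list alone), with a median of 1.03 (adjusted p = 7.1e-11, and adjusted p = 0.19 with an estimated correlation), including Cd68 at 1.05, the complement gene C1qb at 1.24 and Fcer1g at 1.18. Of 25 cytokine, chemokine and NF-kB target genes, 8 rose (9 adjusted over the list alone), with a median of 0.11 (adjusted p = 0.0015, and adjusted p = 0.18 with an estimated correlation). Il1b rose by 1.65, Ptgs2, the inducible cyclooxygenase gene, by 1.53 and Saa3 by 3.05. This list was not called without the dimmer 50% of genes, where its median was higher (0.32, adjusted p = 0.074). The median was 0.03 without control 1, 0.20 without control 3, 0.21 without cKO 1 or the dimmest 25% of genes, and 0.16 to 0.25 with the other scalings or array weights. Of 16 neutrophil genes, 4 rose (5 adjusted over the list alone), with a median of 0.26 (adjusted p = 0.014, and adjusted p = 0.19 with an estimated correlation). All 16 had control means below 7, the median control value of all genes, and the list was not called without the dimmest 25% of genes (median 0.11, adjusted p = 0.37). Of 23 interferon response genes, 2 fell (0 adjusted over the list alone by limma, 7 at unadjusted p under 0.05), with a median of -0.60 (adjusted p = 0.0038, and adjusted p = 0.62 with an estimated correlation). The list medians were 7.19, 8.74 and 8.33 in controls 1, 2 and 3 and 7.46, 7.42 and 7.40 in cKO 1, 2 and 3, so control 1 lay below the cKO arrays. The call was lost without control 2 (median -0.24, adjusted p = 0.097) and by fry (adjusted p = 0.23), and without control 1 the median was -0.94. The lymphocyte list (1 of 18 higher, Ptprc at 1.04, adjusted p = 0.99), the mast cell list (0 of 12 past the threshold by limma, 3 at unadjusted p under 0.05, adjusted p = 0.96) and the erythroid list (1 of 9 higher and 1 lower, Fech at -0.69, adjusted p = 0.67) did not pass.

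The 4 mesenchymal lists were called higher. Of 23 fibroblast and extracellular matrix genes, 21 rose, also adjusted over the list alone, with a median of 0.78 (adjusted p = 1.1e-15, and adjusted p = 0.17 with an estimated correlation). Eln, the elastin gene, rose by 1.81 (SE 0.20), the proteoglycan gene Bgn by 1.33 (SE 0.12) and the fibroblast receptor gene Pdgfrb by 1.02 (SE 0.11). Of 18 smooth muscle genes, 17 rose (18 adjusted over the list alone), with a median of 0.86 (adjusted p = 9.3e-15, and adjusted p = 0.18 with an estimated correlation), including the desmin gene Des at 1.35 and Kcnmb1 at 1.47. Of 10 mesothelium genes, 6 rose (7 adjusted over the list alone), with a median of 0.80 (adjusted p = 4.4e-05, and adjusted p = 0.29 with an estimated correlation). Lrrn4 rose by 1.21, and 2 others, Krt8 and Krt19, are also epithelial. Of 8 genes of the interstitial cells of Cajal, the gut pacemaker cells, 3 rose (4 adjusted over the list alone), with a median of 0.31, or 0.63 without the dimmer 50% of genes (adjusted p = 0.0038, and adjusted p = 0.30 with an estimated correlation), including Thbs4 at 2.04 and Gja1 at 1.14. Kit, their defining receptor gene, differed by 0.46 (adjusted p = 0.063). Nerve and vessel lists had smaller medians. Of 23 enteric neuron and glia genes, 3 rose (4 rose and 1 fell adjusted over the list alone), with a median of 0.29 (adjusted p = 0.0028, and adjusted p = 0.29 with an estimated correlation). Vip rose by 1.35, and the list was not called without the dimmer 50% of genes (adjusted p = 0.18). Of 20 endothelial genes, 1 rose (0 adjusted over the list alone by limma, 6 at unadjusted p under 0.05), with a median of 0.19, or 0.28 with median centring (adjusted p = 0.0059, and adjusted p = 0.18 with an estimated correlation), and Pecam1 differed by 0.33 (adjusted p = 0.095).

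**Figure D2:**
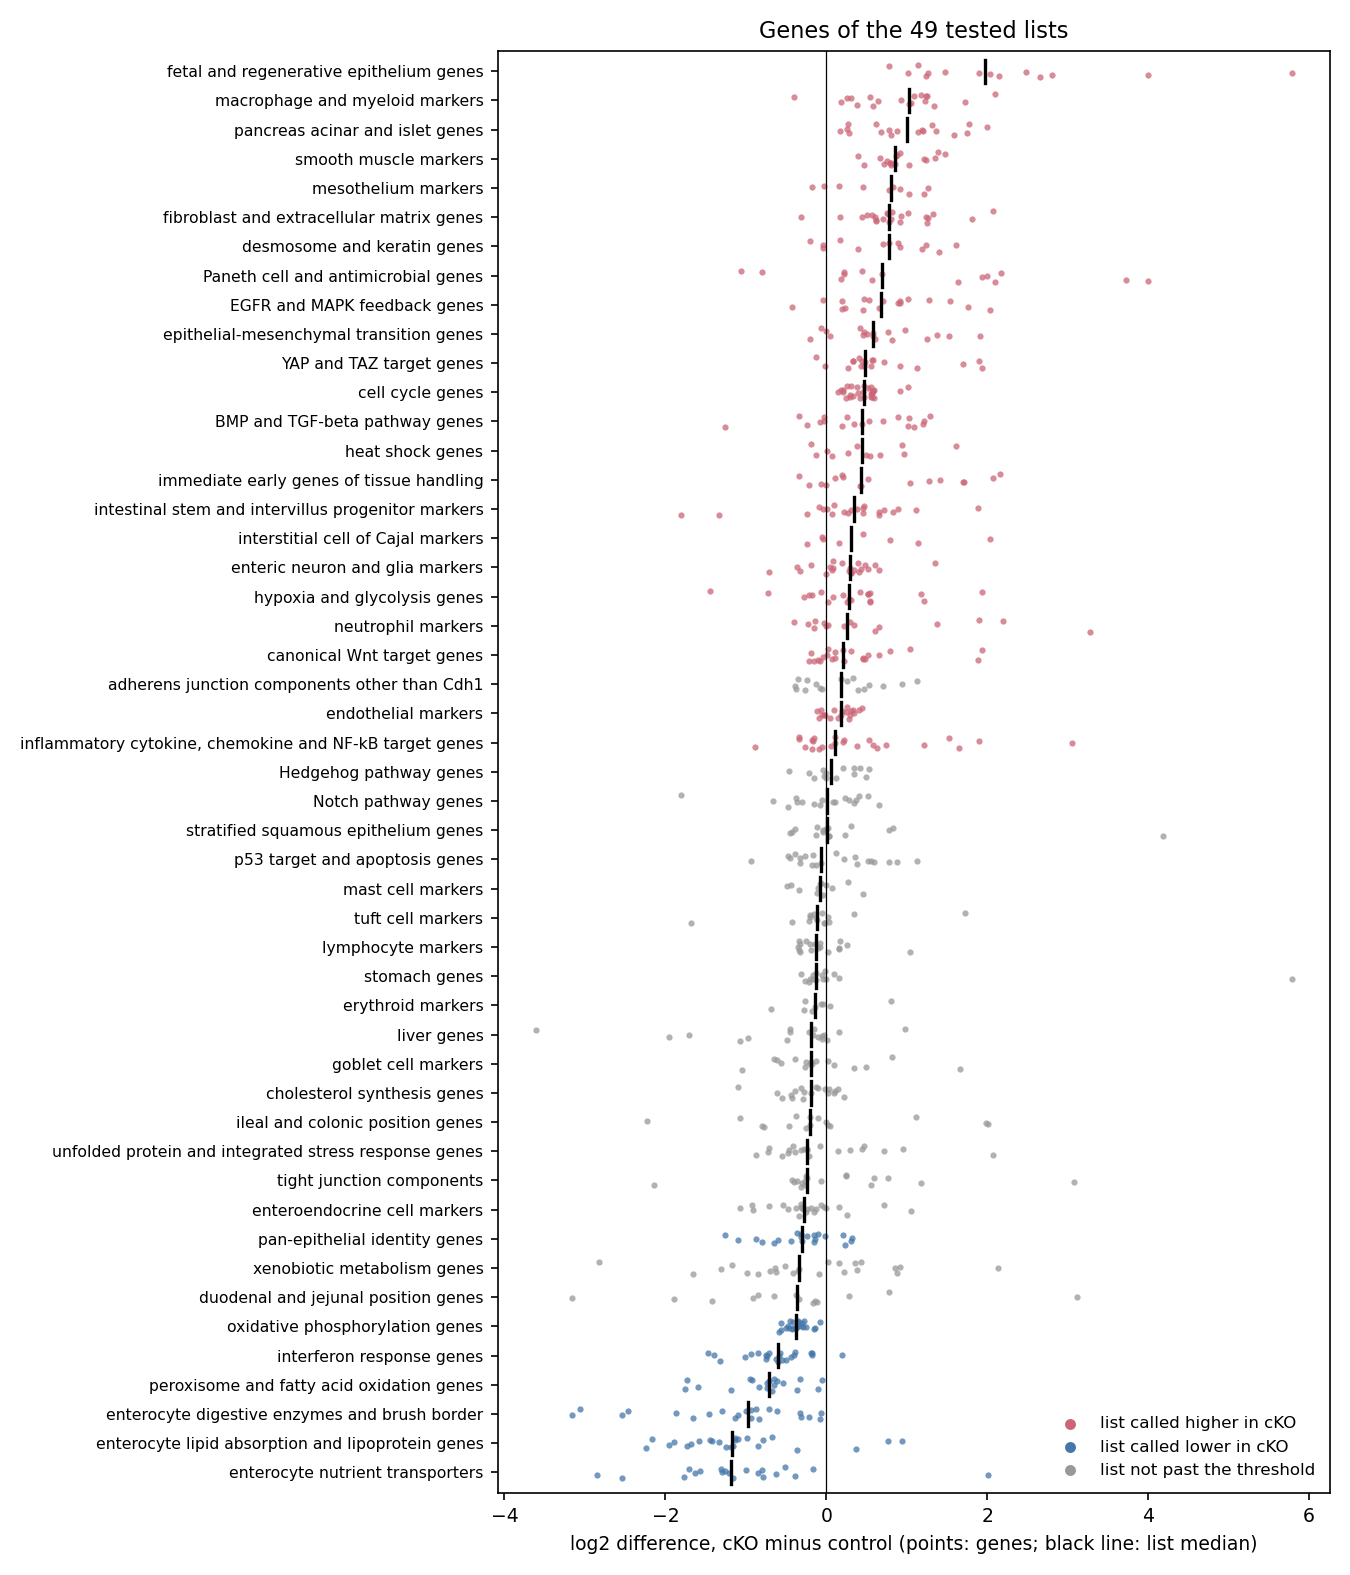
Log2 difference between cKO and control (horizontal axis) of each measured gene in the 49 tested lists (vertical axis); points are genes, black lines are list medians, and colours give the camera result with the preset correlation. The fetal and regenerative list has the highest median, 1.97, and the nutrient transporter list the lowest, -1.19.

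Pancreas genes stood out on 1 array. The pancreas list was called higher (median 1.01, adjusted p = 0.0057, and adjusted p = 0.62 with an estimated correlation), although 0 of its 18 members passed in limma, over all genes or over the list alone, and 1 did at unadjusted p under 0.05. By fry the list was not called (adjusted p = 0.46). All 18 members had their highest value on cKO 3. The chymotrypsinogen gene Ctrb1 read 12.39 there and 5.62 to 7.03 on the other arrays, and Cpb1, a carboxypeptidase gene, 11.12 against 5.23 to 5.61. Both were chosen after their values were seen. Other members stood out less: Ptf1a and Iapp on cKO 3 lay 0.24 and 0.62 above the highest other array. Without cKO 3 the median of the list was -0.21 (adjusted p = 0.39), and with array weights it was 2.40. Of 18 liver genes, 4 fell (list adjusted p = 0.071), Afp among them. This list was called lower with the replicate block (0.013), with median centring (0.032), with array weights (0.040), by fry (0.023) and without control 3 (0.036). Cps1, which the intestine also expresses, fell by 1.07 (SE 0.18). Sex-linked genes set control 1 apart: Xist, expressed from the inactive X chromosome, read 7.43 there and 4.84 to 5.0 on the other arrays, and the Y-linked genes Uty and Eif2s3y read 3.33 and 4.21 there against 6.94 to 7.69 and 8.01 to 8.31.

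**Figure D3:**
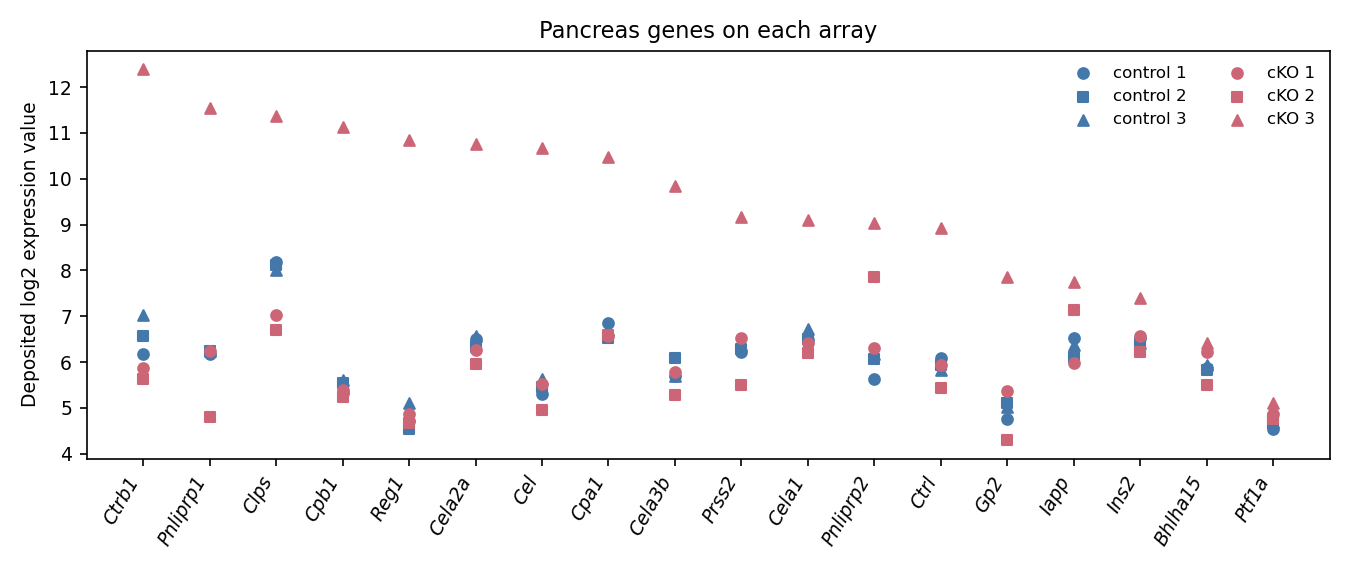
Deposited log2 expression values (vertical axis) of the 18 measured pancreas genes on each of the 6 arrays, 1 point per array, with controls in blue and cKO in red. All 18 genes are highest on cKO 3, with Ctrb1 at 12.39.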

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

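The tests given here for the number of changed genes, for the share of epithelial cells, for the sex-linked genes of control 1 and for the pancreas genes were chosen after those results were seen, and the tests of cKO 1 were set before theirs.

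Probe sets outside the named genes also carried differences. Of the 12102 probe sets with no gene listed, 9 were higher and 14 lower in cKO, and of the 1621 with several genes, 6 were higher and 15 lower (limma, adjusted within each set). They drew attention because they lie in data that the comparison of named genes did not use.

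Among the 10 splits of the 6 arrays into 3 and 3, 1, the real split, gave as many as 2825 genes, and the highest count of the others was 0 (limma, 144 to 889 genes at unadjusted p under 0.05). With 10 splits the share cannot fall under 0.05, so this test is too small to weigh chance.

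The lower enterocyte lists and higher fibroblast and smooth muscle lists could come from a smaller share of epithelial cells in the cKO samples. That would lower all epithelial genes alike, but the median of the 21 identity genes lay 0.83 above that of the 66 enterocyte genes (-0.31 against -1.14, 95% bootstrap interval of the difference 0.58 to 1.10). It would also raise the other cell types alike, but the medians of the endothelial, nerve, fibroblast and smooth muscle lists spanned 0.675, from 0.19 to 0.86 (permutation of list membership over genes, p = 2e-04). The interval and this p took genes as independent, although estimated correlations were 0.27 in the fibroblast and 0.51 in the lipid absorption list. They therefore measure no spread between samples. Only 12 of 23 nerve genes lay above the median control value, against 17 of 20 endothelial genes, and changes of dim genes may read too small. Relative to the control mean, the identity list shifted by -0.37 to -0.25 on the cKO arrays and the 3 enterocyte lists by -1.40 to -0.96. The endothelial list shifted by 0.14 to 0.17 and the fibroblast list by 0.75 to 0.92. These array values argue against a smaller epithelial share as the whole cause. The sex-linked difference of control 1 as the whole cause is argued against as well. Without control 1 the medians of the 3 enterocyte, the fibroblast and the smooth muscle lists were at least 1.01 times those with all arrays. The array means of the groups did not overlap in 5 of 5 lists. A smaller share as part of the cause, added mesenchyme, or a change of enterocytes, in number or expression, tied to the knockout stay open. Whole intestine was measured, which cannot separate the number of enterocytes from the expression within them.

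Pancreas genes were high on cKO 3, and pancreatic tissue taken with that sample is a candidate explanation. All 18 measured members had their highest value there (Ctrb1 at 12.39, Pnliprp1 at 11.54), and in a second list of acinar genes outside the fixed lists 80% did (12 of 15, with Try10 at 11.54 and Try5 at 11.16, but not Ctrc, Spink1 and Tmed6). The genes named as examples were chosen after their values were seen. Of the 18, 1 belongs to another list and 1 lay above the median control value, so few are genes the control intestine expresses strongly. A response to the loss of E-cadherin is argued against, since 11.1% of the members (2 of 18) were higher on all 3 cKO arrays than on all 3 controls. Expression of these genes within the intestine of that sample stays open and was not tested.

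Cdh1 on cKO 1 lay close to the controls, which could mean a mislabelled control. Against this, over the 2713 genes called between the controls and cKO 2 and 3, cKO 1 showed a median share of 0.784 of the change (interquartile range 0.559 to 0.963), and 79.3% of these genes lay past the midpoint. For compressed signal on that array, the interquartile range of its values, 2.92, lay within the 2.83 to 3.16 of the other arrays. The authors' processing, which is not given, may have evened out the spread of the arrays. This range therefore cannot decide whether the signal on cKO 1 was compressed. A less complete deletion of Cdh1 in that sample stays open and was not tested.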

How the results depend on the processing

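Cyclic loess normalization was chosen after the data had been seen, and the other alternatives before.

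The 2825 changed genes became 3243 with quantile normalization, 2581 with median centring of each array and 3138 with cyclic loess, of which 2675, 2334 and 2699 were among the 2825, and the share of higher genes went from 48.1% to 56.4%, 57.7% and 53.6%. Array weights gave 5834 genes (2921 higher, 2913 lower), and testing every probe set on its own gave 1870 (821 higher), with 35512 tests in place of 19938. The weights were 1.06, 2.73 and 0.73 for controls 1, 2 and 3 and 0.60, 0.27 and 2.98 for cKO 1, 2 and 3. Calls with array weights therefore rest mostly on control 2 and on cKO 3, the array with high pancreas genes. The cause of the higher count with array weights was not tested. Leaving out 1 array gave 1226 to 2713 changed genes, 509 to 1275 higher and 717 to 1438 lower, with the lowest counts without control 2. Without control 3 or cKO 3 they were 1505 and 1517. Fewer arrays leave fewer degrees of freedom. Cdh1 stayed lower under every alternative. Its difference of -0.95 did not pass the threshold in the primary comparison (adjusted p = 0.088). It passed without the dimmer 50% of genes (adjusted p = 0.044) and with an intensity trend (0.048), with array weights (-0.886, adjusted p = 0.011) and without cKO 1 (-1.30, adjusted p = 0.012). It ranged from -1.30 to -0.64 with 1 array left out, and its adjusted p over the alternatives from 0.011 to 0.256.

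Of the 23 lists called higher and 7 lower, 0 and 0 were called by camera with an estimated correlation (12 lists at unadjusted p under 0.05). With fry, which tests for a shift in 1 direction and not against other genes, 22 were higher and 8 lower. The pancreas list reversed without cKO 3, to a median of -0.205, and its other medians with 1 array left out reached 1.68. In the other fits 26 to 30 of the 30 calls were kept, and 26 was reached without the dimmer 50% of genes, where 2 calls were lost and 2 lists were not tested. Tested by probe set, Ada, Afp, Cdh3, Cox4i1, Defa24, Hnf4a, Ly6g, Mptx1, Plekha7, Reg3b, Reg3g, Sdhb and Zg16 lost their calls. Of the genes named and not past the threshold, Alpi, Cdh2, Chga, Kit, Mki67, Pecam1, Reg1 and Vil1 were called in at least 1 alternative. No named gene changed direction past the threshold in any alternative. With an array left out, calls of named genes were lost 172 times and gained 11 times, and in the other alternatives 72 and 100 times.

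The replicate numbers did not pair the samples: same-numbered arrays had correlations of -0.08, 0.13 and 0.14 between their deviations from the group means, and not every array correlated best with its own number. With the replicate block 2212 genes were called (989 higher, 1223 lower). Leaving out the dimmest 25% or the dimmer 50% of genes gave 3431 and 3311 changed genes, and the neutrophil list, whose genes are dim, lost its call without the dimmest 25% (adjusted p = 0.37).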

Other observations

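The gene families and the genes named in this part were chosen after their values were seen, and no explanation of them was tested.

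Families defined by a shared symbol stem, 454 in all, were compared with the calls among all genes (hypergeometric test, Benjamini-Hochberg over both directions). All genes include receptor families that were rarely called, such as 1027 Olfr genes (4 higher, 30 lower) and 167 Vmn genes (2 higher, 3 lower). A family may pass only because the intestine expresses it. The test also takes members as independent, so its p-values serve to rank families. Several families share members with the fixed lists, such as the collagens with the fibroblast list and the annexins with the fetal list. Their counts are therefore not separate evidence. Of 12 integrin alpha chains, 7 were higher (adjusted p = 5.9e-04), including the collagen receptor genes Itga1 at 1.22 (SE 0.11) and Itga2 at 1.03 (SE 0.12). Of 44 collagen genes, 14 were higher and 1 lower (adjusted p = 1.6e-04 for higher) and the median was -0.11, with Col18a1 at 1.32 (SE 0.11) and Col12a1 at 1.29 (SE 0.13). Of 12 annexins, 6 were higher (adjusted p = 0.0058), including Anxa1 at 2.80 (SE 0.31) and Anxa2 at 1.01 (SE 0.14). Of 22 matrix metalloproteinases, 7 were higher (adjusted p = 0.032), including Mmp13 at 1.32, Mmp19 at 1.32 and Mmp14 at 0.98. Of 7 insulin-like growth factor binding proteins, 4 were higher (adjusted p = 0.041), with Igfbp2 at 2.10 (SE 0.33). These families had at least as many members higher after quantile normalization and cyclic loess, and with median centring 5 annexins were. The named genes in this paragraph passed the threshold in each alternative, with 1 array left out as well. The control values of Mmp19 lay at background.

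Solute carriers led the lower genes, with 73 of 364 lower and 27 higher (adjusted p = 2.1e-12 for lower). Atp and Ndufb genes came next by adjusted p, and of 224 Tmem genes 35 were lower and 12 higher, and of 70 Rab genes 15 and 6 (adjusted p = 0.0024 and 0.012 for lower). Of 11 UDP-glucuronosyltransferase genes, 6 were lower (adjusted p = 0.0053), including Ugt2b37 at -2.17 (SE 0.22) and Ugt2b38 at -2.07 (SE 0.18). Of 15 aldo-keto reductase genes, 8 were lower and 2 higher (adjusted p = 5.9e-04 for lower), with Akr1c14 at -2.51 (SE 0.33) and, in the opposite direction, Akr1b8 at 2.47 (SE 0.22). The cKO values of Ugt2b37 and Akr1c14 and the control values of Akr1b8 lay at background, so these differences are not exact. Of 13 acyl-CoA thioesterase genes, 6 were lower and 3 higher (adjusted p = 0.013 for lower), with Acot4 at -2.01 (SE 0.13). Of 79 genes with the stem Atp, 22 were lower and 3 higher (adjusted p = 1.5e-05 for lower), among them subunits of the vacuolar proton pump such as Atp6v0b at -0.92 (SE 0.11) and Atp6v1b2 at -0.73 (SE 0.12). Of 9 Ndufb genes of respiratory complex I, 7 were lower (adjusted p = 1.1e-04), and of 25 Cox genes 9 were. With median centring these became 11 Atp, 1 Ndufb and 4 Cox genes, the lower aldo-keto reductase genes 5 and the lower Rab genes 9, so these counts depend on how the arrays are scaled. The lower UDP-glucuronosyltransferase genes numbered 5 to 7 and the lower acyl-CoA thioesterase genes 6 to 7 over the scalings.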
